A study of Caenorhabditis elegans with 2 samples.

How the data were processed

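AKIR-1::GFP chromatin immunoprecipitation was sequenced from whole young adult worms in 2 biological replicates, numbered 3 and 4 per the labels. The labels give sonication, a fragment size range of 200 to 800, and an antibody against GFP. The authors deposited 4 peak lists on ce11: 1 per replicate, called per sample, 1 from both replicates pooled, and an IDR-thresholded list made from the replicate and pooled lists, as the texts deposited with them state. Each call also used 1 further alignment set shared by all of them. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

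The signal value of each peak is as the authors deposited it, on a scale that is not stated and that differs between lists, so it was used only to rank and describe peaks within a list or, on a log2 scale, for correlation across peaks. The −log10 q-value of each peak is also the authors' deposited value, and was only described. Summits were taken from the deposited summit offsets. A number of 0 columns of the shared lists was left without a group. The lists hold no read counts, so depth per sample is unknown and no interval for counting reads is given. Intervals of shares are at 95% and cover counting error over peaks or genes only. As peaks and genes are the units of the tests, p-values describe these lists and not the spread between animals.

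Genes came from Ensembl release 115 of the same assembly, with 46926 genes of which 19985 were protein-coding, and mitochondrial gene symbols came from RefSeq. Sequence came from the RefSeq assembly, whose chromosome lengths match. A promoter ran from 500 bp upstream to 100 bp downstream of any transcript start, and a gene was bound when a summit lay in its promoter. A summit was put in the first class that applied, in the order promoter, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. N is the number of IDR-thresholded peaks, 400. Replicate overlap and annotation classes were compared with 1000 random placements of each peak on its own chromosome, a permutation test over peak positions, chromosome counts with an exact binomial test against the share of nuclear length, and 33 gene lists with Fisher's exact test against other protein-coding genes, or all genes for non-coding lists. List ranks in the pooled list were tested with 100000 resamples of genes. Words of 6 bases were counted in windows of 75 bp on either side of summits and in windows shifted by 300 bp. Benjamini-Hochberg adjustment was used with a threshold of 0.05.

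Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names genes at the 20 strongest IDR-thresholded peaks, up to 4 bound members per list with the highest signal, and akir-1 and unc-119. For tRNA genes, whose strongest members are mitochondrial, the 4 strongest nuclear genes were named instead, a choice made after the values were seen. Alternatives were the stronger 200 peaks, the N strongest peaks of either replicate or of the pooled list, other overlaps, other numbers of peaks, other promoters (1000 bp upstream to 200 bp downstream, and 250 bp on either side), any overlap with the promoter, 1 gene per peak within 2000 bp, rotation of summits, ranks, and other word windows and references. Settings without mitochondrial peaks, with protein-coding starts only, without piRNA genes, and without summits at small RNA genes were added after the data were seen. With groups of 2, no test for outlying samples applies.

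The tests were tried on simulated data. With 10-fold weights on the ribosomal protein genes among 19985 protein-coding genes, the list enrichment test called them in 82% of 50 simulations, and it called any list in 2% of simulations with no raised list. The rank test called the list of 79 ribosomal protein genes, raised by 0.8 SD, in 100% of 50 simulations and any list in 6% without one, over 46926 genes. The simulated values had no ties, whereas most genes in the data have no pooled peak and share the lowest value. These rates may therefore not hold for the data, nor for smaller lists. Word counts recovered a planted word in 100% of 20 simulations over 2080 words, and called any word in 5% without one. Both simulated groups came from the same random windows. In the data the summit windows had 46.9% GC against 36.2% in flanks of the same summits, so the rate of 5% may not hold there. The placement test of the promoter share passed for 7% of sets of 400 randomly placed peaks. All 12 overlap counts compared equalled those of bedtools. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.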

Results

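Chromatin immunoprecipitation with sequencing mapped where AKIR-1, the worm akirin, lay on the genome of young adult Caenorhabditis elegans. Akirins are conserved nuclear proteins that take part in transcriptional regulation, and akir-1 is required for the induction of antimicrobial peptide genes in the infected epidermis. The worms carried an AKIR-1::GFP transgene under the akir-1 promoter, and chromatin of whole animals of mixed sex, 70 hours old, was precipitated with an antibody against GFP. The design has 1 group of 2 biological replicates, numbered 3 and 4, so the comparisons are between replicates and between peaks and the annotated genome. The lists give positions and scores of peaks and no read counts, so the sequencing depth behind them is unknown. All coordinates are on ce11, counted from 1.

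The IDR-thresholded list held 400 peaks. Its strongest peaks lay on the mitochondrial genome: 15 of the 20 highest signal values were mitochondrial. The strongest of all, at position 12302 to 12730 in a coding exon, had a signal value of 6567, and the next, at 4445 to 4959 inside CYTB, the gene of cytochrome b, had 5481. A peak in COX1, which encodes a subunit of cytochrome c oxidase, reached 2922. The peak upstream of the mitochondrial ribosomal RNA gene KEF34_r01 reached 2526. A further peak, of 2073, lay inside KEF34_r01, with its summit 225 bp upstream of ND3, a complex I gene. The strongest nuclear peak, on chromosome I from 10517147 to 10517327, had a signal value of 390.2, and its summit lay 64 bp upstream of the snoRNA gene F59C6.15. The other nuclear peaks among the 20 lay 60 bp upstream of tasp-1 on chromosome III (373), 19 bp upstream of sls-2.4 on chromosome I (291), which encodes an SL2 spliced leader RNA, and in intergenic sequence nearest to the starts of K12H4.5 on chromosome III (312) and eel-1 on chromosome IV (294).

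The replicate 3, replicate 4 and pooled lists held 30000 peaks each. Mitochondrial peaks numbered 12, 18 and 17 in these lists and 16 in the IDR-thresholded list, where they covered 35.6% of the mitochondrial genome of 13794 bp. The median signal value was 1543 over the mitochondrial and 133 over the 384 nuclear IDR-thresholded peaks. Signal values are the authors' own and each list has its own scale. The q-values of the IDR-thresholded peaks ran from 0.0264, shared by 247 of them, to 0.0530, and those of the pooled list reached 0.802. The lowest q-value was 0.0867 in the replicate 3 list and 0.0180 in the replicate 4 list. All 400 IDR-thresholded peaks were among the 400 strongest pooled peaks.

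The replicates shared about as many of their 400 strongest peaks as they did not share, and a smaller share of the 800 to 4000 strongest. Of the 400 strongest peaks of replicate 3, 201 overlapped one of the 400 strongest of replicate 4 by at least 1 bp (50.2%, 95% Wilson interval 45.4 to 55.1). In the other direction 199 did (49.8%, 44.9 to 54.6). Random placement of the replicate 3 peaks on their own chromosomes gave a mean of 2.57% and at most 4% (one-sided permutation p = 0.001 over peak positions, the smallest that 1000 placements can give). On the nuclear chromosomes alone 189 of 388 replicate 3 peaks were shared (48.7%), against 0.293% by placement. The share of replicate 3 peaks was 41.1% among the 800 strongest of each replicate, 31.5% among 2000 and 30.1% among 4000, against 1.72%, 1.97% and 3.24% by placement. Over all 30000 peaks of each list it was 46.3%, where placement alone gave 21.4%.

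Nearly all IDR-thresholded peaks were found in both complete replicate lists: 394 overlapped a replicate 3 peak, 397 a replicate 4 peak and 391 both (97.8%, 95.8 to 98.8). The IDR-thresholded list was made from the replicate and pooled lists, so this share is not an independent measure of reproducibility. The nuclear peaks were in both for 381 of 384 and the mitochondrial ones for 10 of 16, as 6 mitochondrial peaks overlapped no replicate 3 peak. Among the 400 strongest of each replicate the numbers were 282, 293 and 199. The log2 signal values of the replicates correlated over 391 peaks with Pearson's r = 0.76 and Spearman's rho = 0.33 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The mitochondrial peaks carried much of Pearson's r, which was 0.33 over the 381 nuclear peaks. On ranks within each replicate list, in place of log2 signal values, Pearson's r was -0.065 (permutation p = 0.077). These ranks follow the order of the signal values, for which rho was 0.33, so agreement in order did not reverse. Over the 13776 pooled peaks that overlapped both replicates r was 0.46 and rho 0.25, and r of the ranks was 0.20. These correlations are across peaks, which are not independent replicates, and the IDR-thresholded peaks were selected on the same signal.

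**Figure D1:**
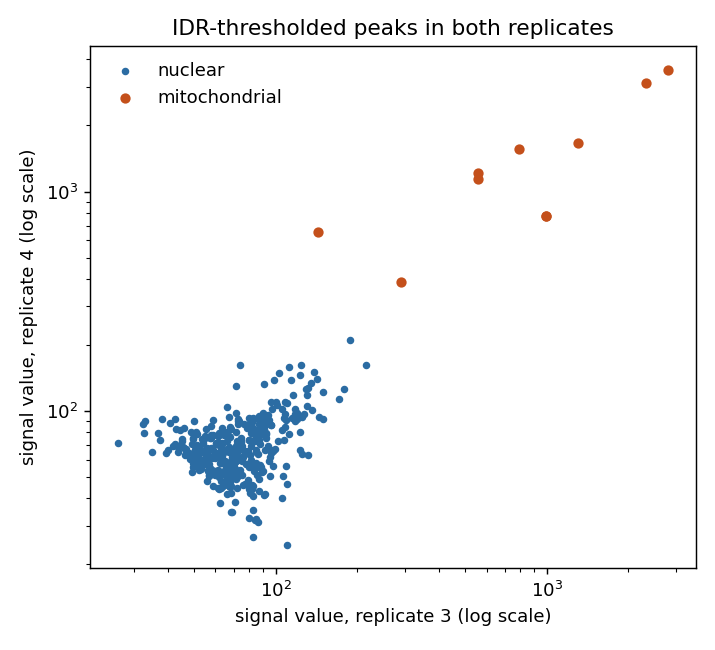
Signal value of each IDR-thresholded peak in replicate 3 (x axis, log scale) and replicate 4 (y axis, log scale), for the 391 peaks found in both lists, nuclear in blue and mitochondrial in orange. The mitochondrial peaks stand at the upper end, and the nuclear peaks form a cloud with a Pearson's r of 0.33 on log2 values.

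Summits lay mainly in promoters, taken as 500 bp upstream to 100 bp downstream of any annotated transcript start. Of the 384 nuclear summits 264 did (68.8%, 95% Wilson interval 63.9 to 73.2), 3.10 times the 22.2% of random placement (one-sided permutation p = 0.001). Introns held 9.64% of nuclear summits against 29.0% by placement, coding exons 5.47% against 20.7%, and intergenic sequence 15.4% against 22.8% (permutation p = 0.001 for each, one-sided for fewer). Outside promoters, which were assigned before 5' UTRs and include the 100 bp after a start, no summit lay in an annotated 5' UTR, where placement gave 0.647% (permutation p = 0.094). With the mitochondrial peaks included the promoter share was 68.2% (273 of 400) against 23.8%. Starts of protein-coding genes alone accounted for 37.5% of the 400 summits, against 15.2% by placement (permutation p = 0.001).

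**Figure D2:**
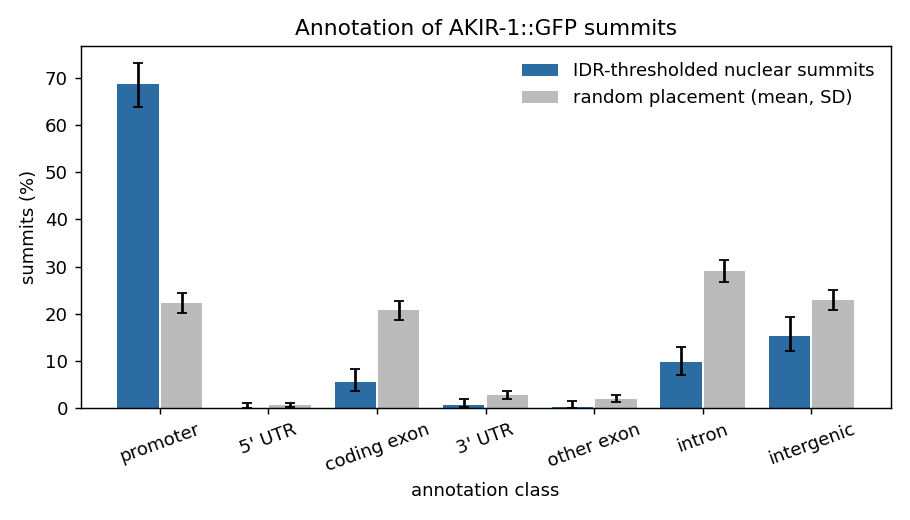
Share of the 384 nuclear IDR-thresholded summits in each annotation class (blue, % with 95% Wilson interval) and mean share of 1000 random placements (grey, with SD). Promoters hold 68.8% of summits against 22.2% by placement, and introns and coding exons hold fewer than placement gives.

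The 264 promoter summits fell at small RNA genes, at protein-coding genes and at other annotated genes. Nuclear tRNA genes had a summit at the promoter in 51 of the 384 nuclear peaks (13.3%), snoRNA genes in 42 (10.9%) and snRNA genes in 6 (1.56%). At least 1 of these classes was present in 98 peaks (25.5%, 21.4 to 30.1). Protein-coding genes without such a small RNA gene accounted for 127 peaks (33.1%), other annotated genes alone for 39 (10.2%), and 120 peaks (31.2%) lay at no annotated start. Summits sat close to the starts of the small RNA genes: the median position was 8 bp downstream of the start for tRNA genes and 40 bp upstream of it for snoRNA genes, with 49 of 51 and 38 of 42 peaks within 100 bp. At nuclear protein-coding genes the median summit lay 193 bp upstream, and 39 of 143 peaks were within 100 bp. Only summits from 500 bp upstream to 100 bp downstream were counted. The protein-coding median lies near the middle of that window, so it does not by itself show a preferred position. At the 9 cytosolic ribosomal protein genes the median was 305 bp upstream.

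**Figure D3:**
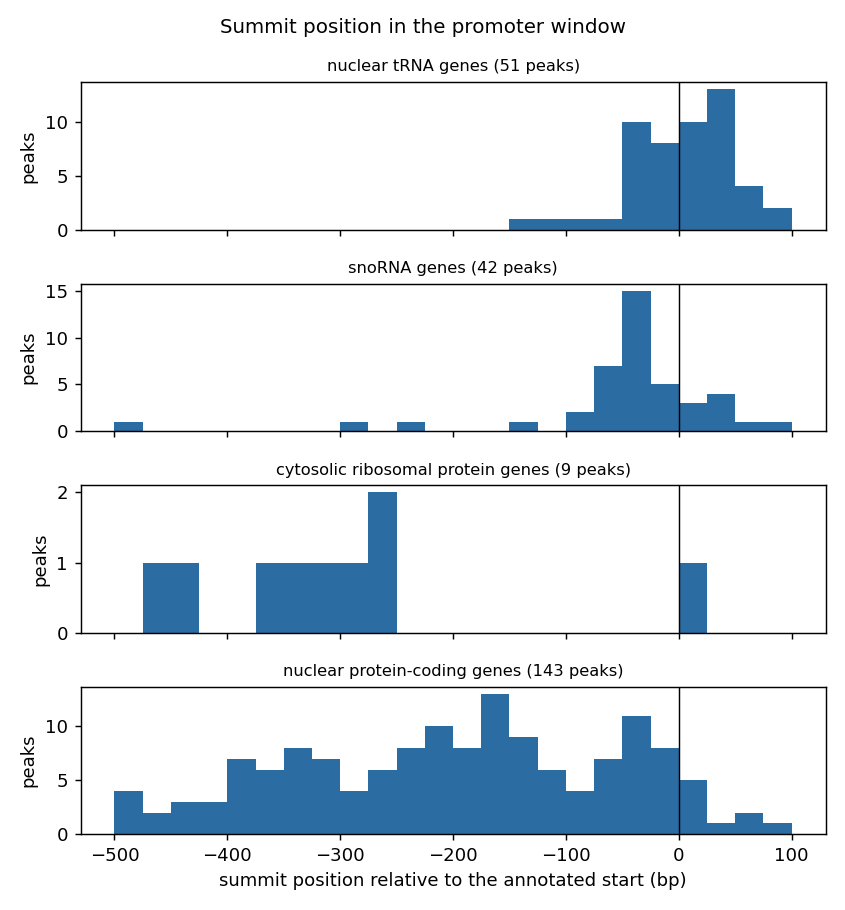
Position of IDR-thresholded summits relative to the nearest annotated start (x axis, bp, negative upstream) for nuclear tRNA, snoRNA, cytosolic ribosomal protein and nuclear protein-coding genes, as the number of peaks per 25 bp. Summits at tRNA and snoRNA genes gather at the start, and those at ribosomal protein genes have a median 305 bp upstream.

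Chromosome X held more and chromosome V fewer nuclear peaks than their lengths give. X carried 97 of 384 peaks (25.3%, 95% exact interval 21 to 29.9) and makes up 17.7% of the nuclear genome (exact binomial test, two-sided, Benjamini-Hochberg adjusted p = 0.00131 over 6 chromosomes). V carried 57 (14.8%, 11.4 to 18.8) against 20.9% (same exact test, adjusted p = 0.00931). Chromosomes I (54 peaks), II (62), III (61) and IV (53) did not pass the test, with adjusted p of 0.668, 0.668, 0.353 and 0.120. III passed with more peaks than its length gives among the stronger 200 peaks (same exact test, adjusted p = 0.0471) and with replicate 4 alone (0.0345), and IV with fewer among the stronger 200 (0.0384). Of the 56 nuclear peaks with a tRNA start within 500 bp, 34 were on X, where 276 of 612 nuclear tRNA genes lie. The X share of the other 328 peaks was 19.2% (15.1 to 23.9).

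**Figure D4:**
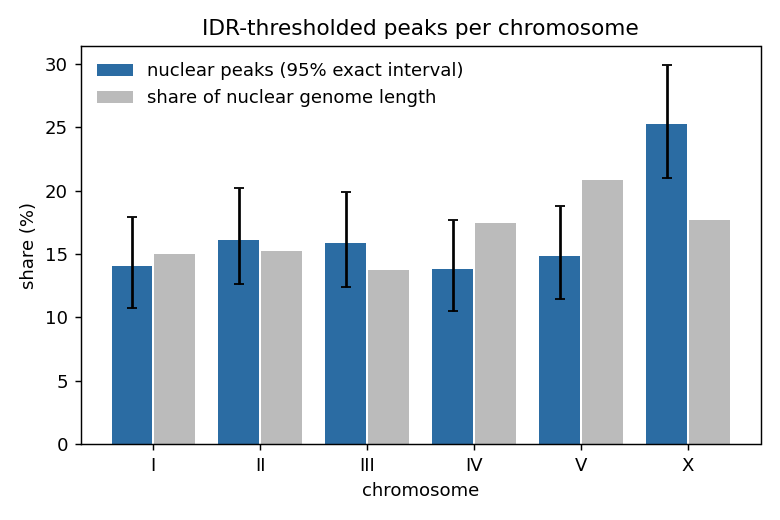
Share of the 384 nuclear IDR-thresholded peaks on each chromosome (blue, %, with 95% exact interval) and share of the nuclear genome length (grey, %). X stands at 25.3% against 17.7% of the genome and V at 14.8% against 20.9%.

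Promoters of tRNA, snoRNA and snRNA genes were bound more often than those of other genes. In all, 434 genes had an IDR-thresholded summit in the promoter, 190 of them protein-coding. Of 634 tRNA genes 71 were bound (11.2%, 95% exact interval 8.85 to 13.9) against 0.784% of other genes (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted p = 7.3e-53 over 33 lists). On the nuclear chromosomes alone 59 of 612 were bound (9.64%, Fisher's exact test, adjusted p = 5.42e-41). The highest nuclear signal values were at C04A11.t1, a leucine tRNA gene on chromosome X from 13665555 to 13665673 (243), at M02F4.t1 and M02F4.t2, neighbouring glycine and glutamate tRNA genes on X that share a summit (209), and at C28G1.t1, a glutamate tRNA gene on X (202). Most tRNA genes have near-identical copies, so which copy a peak belongs to is uncertain: of the 33 nuclear tRNA genes with a unique neighbourhood none was bound, against 59 of the 579 with a repeated one (Fisher's exact test, two-sided p = 0.0630).

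The snoRNA genes, whose products guide chemical modification of ribosomal RNA, had 42 of 346 members bound (odds ratio 16.3, 95% interval 11.3 to 22.9, Fisher's exact test, adjusted p = 1.55e-32). F59C6.15 on I (390.2), ZK994.7 on V from 8500579 to 8500645 (289) and the neighbours C51F7.3 and C51F7.4 on V, which share a summit (222), led them. The genes annotated as snRNA had 7 of 129 bound (5.43%, 2.21 to 10.9, Fisher's exact test, adjusted p = 0.00138). Their strongest were sls-2.4 on I (291), R07E5.16 on III (216), sls-2.1 on II (188) and sls-2.8 on III (183). Of 261 microRNA genes 6 were bound (2.30%, Fisher's exact test, adjusted p = 0.130), among them mir-51, mir-52, mir-58a and mir-80 with signal values of 143, 134, 133 and 128. That list passed with promoters of 250 bp on either side (Fisher's exact test, adjusted p = 0.0418). It also passed with summits rotated along their chromosomes, where 0.676 members were bound on average (permutation, adjusted p = 0.0147). Rotation compares with random positions and not with other genes, so the general excess at promoters counts toward that pass. With the main promoter and piRNA genes left out of the background, the microRNA list did not pass (Fisher's exact test, adjusted p = 0.550). Of 22 rRNA genes 1 was bound, the mitochondrial KEF34_r01 (Fisher's exact test, adjusted p = 0.610).

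**Figure D5:**
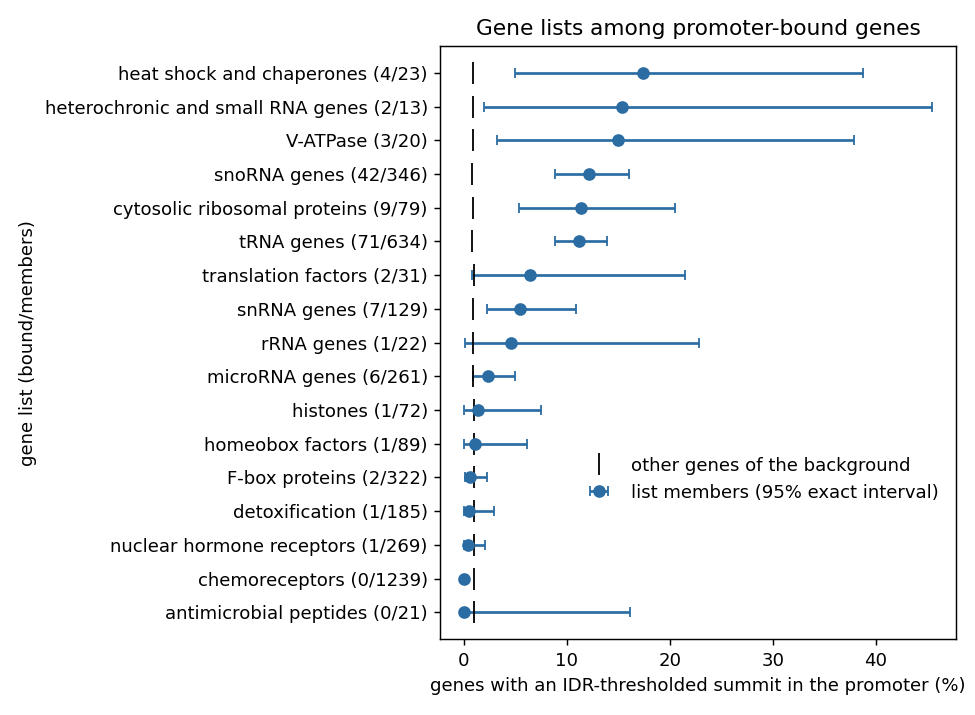
Share of each list's genes with an IDR-thresholded summit in the promoter (x axis, %; points, with 95% exact interval) and share of the other genes of its background (ticks), for lists with at least 1 bound gene and for chemoreceptors and antimicrobial peptides. The tRNA list stands at 11.2% and the snoRNA list at 42 of 346 genes, and chemoreceptors at 0 of 1239.

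Among protein-coding lists, genes of the ribosome, of chaperones and of the vacuolar proton pump were over-represented. A summit at any transcript start made a gene bound, and genes were not matched on the number of starts. Lists rich in genes with many starts can therefore hold more bound genes for that reason alone. Of 79 cytosolic ribosomal protein genes 9 were bound (11.4%, 5.34 to 20.5) against 0.909% of other protein-coding genes (Fisher's exact test, one-sided, adjusted p = 6.7e-07). They included rpl-3 on III (256), rpl-15 on IV (241), rpl-35 on III (214) and rps-1 on III (183). With promoters of 250 bp on either side 1 of 79 was bound (Fisher's exact test, adjusted p = 1). Of 23 heat shock and chaperone genes 4 were bound (17.4%, 4.95 to 38.8, Fisher's exact test, adjusted p = 0.000502): dnj-13 on II (216), hsp-90 on V (189), hsp-3 on X (161) and hsp-1 on IV (108). The hsp-90 summit lay inside the annotated gene, 362 bp upstream of a later transcript start. With 1 gene per peak the chaperone call was lost (Fisher's exact test, adjusted p = 0.535).

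Of 20 V-ATPase genes 3 were bound, vha-12 on X (138), vha-13 on V (115) and vha-8 on IV (110) (15%, 3.21 to 37.9; Fisher's exact test, one-sided, adjusted p = 0.00471). None of the 20 was bound by the 400 strongest peaks of replicate 3 alone. The call was also lost with the stronger 200 peaks (Fisher's exact test, adjusted p = 0.391) and with promoters of 250 bp on either side (0.523). Of 13 heterochronic and small RNA genes 2 were bound, mir-51 and mir-52 (Fisher's exact test, adjusted p = 0.0293), a call lost without replicate 3 (adjusted p = 0.384), with 1 gene per peak, and without piRNA genes in the background. Of 31 translation factor genes 2 were bound, eef-1A.2 (130.1) and eif-3.E (127) (Fisher's exact test, adjusted p = 0.130). With 3 bound, that list passed with promoters of 1000 bp upstream to 200 bp downstream (Fisher's exact test, adjusted p = 0.0407). It also passed with summits rotated along their chromosomes, where 0.07 members were bound on average (permutation, adjusted p = 0.0124). That comparison is again with random positions and not with other genes.

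No antimicrobial peptide gene of the nlp and cnc families had an IDR-thresholded summit in its promoter (0 of 21, exact one-sided adjusted p = 1 for over-representation, odds ratio at most 20.2). The same held for 16 genes of epidermal immune signalling, 10 of the NuRD and MEC complexes, 13 of the SWI/SNF complexes, 33 of the proteasome and 66 mitochondrial ribosomal protein genes. It also held for cuticle collagens (0 of 174), vitellogenins (6), body wall muscle (28), pharynx (17), epidermis (26), intestine (19), germline and meiosis (42), major sperm proteins (31), neurons (31), and C-type lectins and lysozymes (256). Only 0.952% of other protein-coding genes were bound, so 0 was the likely count for most of these lists and does not show absence of binding. Rotated summits bound 0.042 antimicrobial peptide genes on average. Even C-type lectins and lysozymes, the longest of these lists, were not under-represented (Fisher's exact test, one-sided p = 0.0853, unadjusted). Single members were bound among histones (his-37, of 72), detoxification genes (gst-27, of 185), nuclear hormone receptors (nhr-68, of 269) and homeobox factors (ceh-38, of 89), and 2 of 322 F-box genes, fbxb-72 and fbxb-85. Chemoreceptors had 0 of 1239 bound and were under-represented (Fisher's exact test, adjusted p = 0.000163), a call lost with the stronger 200 peaks (0.0744). Rotation of summits along their chromosomes could not test this call. It bound only 2.46 chemoreceptor genes on average, so even 0, the lowest possible count, did not pass (permutation p = 0.087, unadjusted). Neither akir-1 on I, from 4137161 to 4138952, nor unc-119 on III had a pooled or replicate 4 peak in its promoter. Replicate 3 had a weak peak in that of akir-1 (signal value 30.7, rank 8662, q-value 0.521).

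The 30000 pooled peaks extended the picture to lists with few IDR-thresholded peaks. Genes were ranked by their strongest pooled peak, and a list's mean rank was compared with that of other genes as percentiles (two-sided permutation test, 100000 resamples, adjusted over 33 lists). A gene's strongest peak was taken over all its transcript starts, and genes were not matched on the number of starts. Lists rich in genes with many starts can rank higher, and those with few lower, for that reason alone. The mean rank was higher for 9 lists and lower for 2, and with other promoter widths or either replicate alone for 10 to 12 and 3 to 5. It was 70.0 for tRNA genes against 49.7 for other genes and 63.3 for snoRNA genes against 49.9 (permutation test, adjusted p = 0.00011 for each). It was 59.6 for cytosolic ribosomal proteins against 49.96 (permutation test, adjusted p = 0.00044), and 63.3 for heat shock and chaperone genes (0.0106).

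Epidermal immune signalling genes had a mean rank of 64.1 against 49.99, and 8 of 16, or 50%, had a pooled peak in the promoter against 23% of other protein-coding genes (permutation test, adjusted p = 0.0225). With replicate 4 alone, without replicate 3, that call was lost (permutation test, adjusted p = 0.099). The antimicrobial peptides had a mean rank of 49.9 (permutation test, adjusted p = 0.99). Their mean exceeded that of other genes by 9.78 with promoters of 250 bp on either side and by 9.83 with promoters of 1000 bp upstream to 200 bp downstream, without passing (permutation test, adjusted p = 0.0578 and 0.117). Heterochronic and small RNA genes (76.5), microRNA genes (55.6), snRNA genes (55.4) and nuclear hormone receptors (54.4) were higher, with adjusted p of 0.000396, 0.000165, 0.0106 and 0.00293. Chemoreceptors (46.4, permutation test, adjusted p = 0.00011) and F-box genes (45.9, 0.0025) were lower. Under at least 1 other setting the call was lost for cytosolic ribosomal proteins (permutation test, adjusted p up to 0.475), heat shock and chaperone genes (0.066) and heterochronic and small RNA genes (0.0578), in each case with another promoter width. Major sperm proteins, at 41.7 against 50.01, did not pass (permutation test, adjusted p = 0.0762) but were lower under each of the 4 other settings (0.0191 to 0.0448). The NuRD and MEC complexes, at 61.3 against 49.99, did not pass (permutation test, adjusted p = 0.204) but were higher with promoters of 250 bp on either side (0.0055), with replicate 4 alone (0.0374) and with replicate 3 alone (0.000198). Body wall muscle genes, with an adjusted p of 0.244 in the same permutation test, were higher with replicate 4 alone (0.0088) and with replicate 3 alone (0.000283). The median pooled peak had a signal value of 44.5 and the weakest 33.6, against 108 for the weakest IDR-thresholded peak, so this ranking includes many weak peaks.

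Sequence under the summits was richer in G and C than its flanks. Windows of 75 bp on either side of the 400 summits had 46.9% ± 8.24 GC (SD over windows), against 36.2% ± 8.31 in windows 300 bp to either side. Of 2080 words of 6 bases 399 were found in more summit windows and 264 in fewer (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over all words). ACGCGC was in 17.2% of summit windows and 1.38% of flanks (Fisher's exact test, adjusted p = 8.76e-21), and GAGAGA in 28.8% and 8.88% (2.4e-15). AAAAAT was in 28.8% and 58.5% (1.45e-19). The calls largely followed base composition: of the 36 words made only of G and C 31 were more frequent and none less, and of the 36 made only of A and T none was more frequent and 34 less. Among 640 words with equal numbers of both kinds 83 were more and 24 less frequent. GAGAGA is one of these 640, whose median share was 5.375% of summit windows and 4.875% of flanks, so its excess does not follow from this count of letters.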

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

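Settings restricted to nuclear chromosomes, to protein-coding starts, without piRNA genes or without small RNA summits were chosen after seeing the data. The promoter share, the V share and the overlap of the replicates' strongest peaks kept their direction and side of the threshold under every setting run for them. The X share did so with the other peak lists, and its excess did not pass among the 328 peaks with no tRNA start within 500 bp (19.2%, exact binomial test, p = 0.469). The pooled list's 400 strongest peaks are the IDR-thresholded peaks, so that setting tests nothing. The stronger 200 peaks gave 227 more frequent words, lost the V-ATPase call (5% bound) and lost the chemoreceptor call (0% bound, Fisher's exact test, adjusted p = 0.0744). Overlap in both replicates was 94.5% at 50% of both peaks, 90% for summits within 100 bp and 99.2% on nuclear chromosomes. Pearson's r of the ranks within the replicate lists was 0.20 over the 13776 pooled peaks found in both, but fell to -0.065 over the IDR-thresholded ones (permutation p = 0.077). The ranks keep the order of the signal values, for which Spearman's rho was 0.33 over the same peaks, so agreement in order did not reverse. Pearson's r gives weight to extreme ranks. The median ranks were 223 in replicate 3 and 225 in replicate 4, but ranks reached 14738 and 15283. V-ATPase genes were bound at 15% without replicate 3 and 0% without replicate 4, and heterochronic and small RNA genes at 7.69% and 15.4%. Promoters of 250 bp on either side left 1.27% of ribosomal protein and 5% of V-ATPase genes bound, and the former had summits a median 305 bp upstream. With 1 gene per peak 4.35% of chaperone genes and 0% of heterochronic genes were bound, since a summit then counts for a single gene. Without piRNA genes the heterochronic list, at 15.4%, had an adjusted p of 0.0622, as other background genes are bound more often. Without summits at small RNA genes snoRNA and snRNA genes were at 0% by construction, and 238 words were more frequent. Rotation could not test the chemoreceptor call, as it bound 2.46 of these genes on average and 0% is the lowest possible share. The cause was not tested for the remaining lost calls. Of 132 list ranks recomputed under other settings 93 kept side and direction, 4 lost and 20 gained a call (major sperm proteins in 4 settings, NuRD and MEC complexes in 3), none with a call turned, and 15 without a call changed sign. Unknown read depth limits the weaker peaks.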

Other observations

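The tests of shared reads for each class of small RNA gene were chosen only after the combined result was seen, and the other tests in this part were fixed beforehand. Further genes for structured RNAs were among the nuclear peaks, named here after their values were seen. The summit at rpr-1, the RNA of RNase P, which trims tRNA precursors, lay 17 bp upstream of its start on chromosome I with a signal value of 251, ranking 24 in replicate 3 and 38 in replicate 4. The summit at mrpr-1, the RNA of RNase MRP, which takes part in ribosomal RNA processing, lay 3 bp upstream of its start on II with 124. A promoter summit of 191 lay 207 bp upstream of lin-35, the worm retinoblastoma homologue, on I. Of 22 U6 genes, transcribed by RNA polymerase III, 1 was bound, and of the 107 other genes annotated as snRNA 6 were (odds ratio between 0.0166 and 7.17, Fisher's exact test, two-sided p of 1). The bound genes among the 107 include the spliced leader genes sls-2.1, sls-2.4, sls-2.8 and sls-2.9, so whether U6 genes are preferred over other spliceosomal RNA genes stays open.

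Peaks at small RNA genes may come in part from reads shared between near-identical copies. Nuclear tRNA, snoRNA and snRNA genes with a unique neighbourhood had an odds ratio of 19 against other nuclear genes (95% interval 13.2 to 27), but 40 of the 41 bound genes behind it are snoRNA genes, so the combined value does not speak for the other classes. For snoRNA genes alone the odds ratio was 22.7 (15.6 to 32.4), which argues against shared reads as the whole cause there. For tRNA genes it was 0 (0 to 17.6), with 0 of 33 bound, and for snRNA genes 5.93 (0.144 to 36.4), so for these classes shared reads and binding cannot be told apart. GC content does not account for the pattern: 25.5% of nuclear summits lay at these genes, against 1.08% and at most 3.91% in 1000 GC-matched placements. Pull-down of heavily transcribed genes by any GFP fusion was not tested, since a control with GFP alone was not analysed here, and no biological explanation was tested.

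The mitochondrial peaks could come from abundant mitochondrial DNA in the extract. Random positions argue against a form of this with no preferred place: summits of replicate 3 lay a median 26 bp from the nearest replicate 4 summit, against 210 bp by placement (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). The test covers the replicate 3 peaks, and 6 of the 16 mitochondrial IDR-thresholded peaks overlapped none of these. Uneven recovery of mitochondrial DNA that recurs in both replicates stays open, as both calls used the same further alignment set, and no biological explanation was tested.

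The excess on chromosome X may follow the tRNA genes, of which 45.1% of the nuclear ones lie on X. Nuclear peaks with no tRNA start within 500 bp had 19.2% on X (15.1 to 23.9), an interval that includes the 17.7% of the genome and lies below the 25.3% of all nuclear peaks. Peaks near a tRNA start had 60.7% on X (46.8 to 73.5). The excess thus lay among peaks near tRNA starts, as a source at tRNA genes would give. The X share of these peaks was above the 45.1% of nuclear tRNA genes, however. Where tRNA genes lie may therefore not account for the whole excess, although peaks and genes are different units. The uncertainty over tRNA copies applies here too. No biological explanation was tested.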
